A study of Mus musculus with 12 samples.

How the data were processed

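RNA was measured in 12 mammary gland libraries from female C57BL/6 mice, a common inbred laboratory strain, at postnatal day 84 and 4 weeks after folic acid supplementation. Per the labels, 6 libraries came from mice given 5 mg/kg folic acid and 6 from mice given 1 mg/kg. Per the labels' protocols, the right thoracic mammary fat pad was taken whole and frozen, RNA was isolated with the mirVana kit, and libraries were made from total RNA with the TruSeq RNA Sample Prep Kit v2, a kit that selects polyadenylated RNA and does not mark strand. A whole fat pad holds fat, epithelium, vessels and immune cells, and the amount of each can vary from pad to pad. The labels do not state that the libraries of a group are separate animals, so every p measures the spread between these samples. The labels give no batch, litter or cage. Replicate numbers follow the order of the records and do not pair samples between groups.

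The authors deposited raw read counts per gene, and per the submitters' processing notes reads were aligned with STAR to mm10 and counted with HTSeq 0.6.1. The version of STAR, the gene annotation and the strand setting of the counting are not given in the sources used here. Each file listed 55487 Ensembl gene IDs and 5 tally lines for reads given to no gene. The tally lines stayed out of library sizes and tests, and they held from 16.7% to 35.7% of all reads tallied. Reads aligned to more than 1 place were among those tallies, at 8.30% to 10.5%, so genes with near-identical copies lose reads. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart. Gene symbols were matched for 55141 IDs and were missing for 346, and coordinates came from GENCODE vM21 on GRCm38, the assembly also called mm10.

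Depth was 48.2 to 75.3 M gene-assigned reads per library, where M stands for mega, with a mean of 60.0 ± 8.35 M at 5 mg/kg and 60.4 ± 7.70 M at 1 mg/kg (SD, n = 6 each). Pairs of libraries within a group were compared by a chi-square of their counts over genes with at least 20 reads in the pair. The lowest value among 30 pairs was 41.7 per degree of freedom, so no library was a copy of another of its group within sampling noise. Pairs between the groups were not compared in this way.

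The main test was edgeR 4.0.16 (R 4.3.3), with filterByExpr by group, TMM normalization, and the quasi-likelihood F-test with robust dispersion estimation. It compared 5 mg/kg with 1 mg/kg over all 12 libraries without covariates, and p-values were adjusted by the Benjamini-Hochberg method over 18647 tested genes, with 0.05 as the threshold. Fold changes are log2 and positive when the level was higher at 5 mg/kg. Standard errors were derived from the fold change and its F statistic, and intervals are 95% intervals. CPM values are read counts scaled to a common library size, computed here from the deposited counts with TMM factors.

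The tests, the rule for named genes and 28 gene lists were fixed before the data were examined. The lists cover folate metabolism, DNA methylation, imprinting, lipid metabolism and the cell types a fat pad can hold. Of their 577 entries, 539 were tested, and 3 older names were resolved through synonyms. Direction was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, using a preset correlation of 0.01 between genes, and again with an estimated correlation. The fry test was run beside it. Members were also adjusted over the list alone. A list level is the mean log2 CPM of the list's tested members in a library, and levels were compared by an exact two-sided permutation test over all 924 assignments of the libraries, whose smallest possible p is 0.00216. Library structure was taken from the 500 most variable genes and compared over the 462 distinct splits into groups of 6.

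Among genes past the threshold with a mean CPM of at least 1, the 6 with the largest fold change and the 6 with the smallest p were to be named in each direction. Predicted gene models and immunoglobulin or T-cell receptor segments were counted but not named. If fewer than 12 genes of a direction passed, the 12 with the smallest unadjusted p and a mean CPM of at least 1 were to be given as values that did not pass. Of every list, the 3 members with the smallest p and the member with the highest mean CPM were to be named, with all members that passed. Folr1, Slc19a1, Mthfd1, Mtr, Dnmt1, Dnmt3a, Dnmt3b, Esr1 and Pgr were among the genes to be named whatever their values. Some genes that the rule names are not reported here. A list could be given as a count with 2 to 4 of its named members. Which of a list's named members the text gives was chosen after their values were seen. The smallest p of all belonged to an ID without a symbol, which is given by its ID.

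Alternatives set in advance were DESeq2 1.42.0, limma-voom with and without sample quality weights, other scalings and filters, other thresholds, covariates for the muscle, luminal, B cell and adipocyte lists, surrogate variables from sva 3.50.0, removal of muscle and epidermis genes, and leaving out each library in turn. Alternatives chosen after seeing the data were the share of reads outside genes as a covariate (as log2 of its ratio to gene reads), fits within libraries of like B cell level, list tests with the B cell level as a covariate, counts of list members with each library left out, and removal of the mitochondrial rRNA genes. The number of genes whose groups do not overlap on CPM was counted after the values were seen, and the number expected by chance takes all assignments of 6 of the 12 libraries as equally likely.

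The test was checked on counts simulated from the real means, library sizes and dispersions for 18647 genes. Each gene was drawn independently, in 1 run per fold change, so these counts held no structure shared between genes. With 200 genes changed, it recovered 0 of them at a 1.5-fold change, 73 at a 2-fold change and 160 at a 4-fold change, with 0, 3 and 10 false calls. With no gene changed it made 0 calls and gave 915 genes at an unadjusted p under 0.05. The real libraries gave 359 such genes, so the simulated recoveries need not hold for them.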

Results

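Mammary gland RNA was compared between 6 libraries from female C57BL/6 mice given 5 mg/kg folic acid and 6 from mice given 1 mg/kg, all at postnatal day 84. Folic acid is the synthetic form of folate, the vitamin that carries 1-carbon units for nucleotide synthesis and methylation. The question was whether the amount taken during juvenile and peri-pubertal life left a difference in the tissue's RNA 4 weeks later. Libraries held from 48.2 to 75.3 M gene-assigned reads. The mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2 together took 46.1 ± 4.86% of them at 1 mg/kg and 49.3 ± 7.01% at 5 mg/kg (mean ± SD, n = 6 each, exact permutation p = 0.383). For 6 measures of library quality no difference between the groups was detected, the smallest exact permutation p being 0.290 for the number of genes detected.

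No gene differed between the 5 mg/kg and the 1 mg/kg mammary glands past the threshold. The genes with the smallest p and higher levels at 5 mg/kg included Pcdh20, a protocadherin, Rap1gap, a GTPase-activating protein for Rap1, the slow-twitch muscle genes Tnnt1 and Myl3, and the epidermal genes Dmkn and Krt10. Those with lower levels at 5 mg/kg included Agps, which makes ether lipids in peroxisomes, Hsph1, a heat shock protein, the DNA topoisomerase Top1, and Upf2, which acts in nonsense-mediated decay. By edgeR's quasi-likelihood test, 0 of 18647 genes passed, with a smallest Benjamini-Hochberg adjusted p of 0.943. At an unadjusted p under 0.05 there were 359 genes, 249 higher and 110 lower at 5 mg/kg, against 932 expected by chance. DESeq2 also gave 0 genes, with 776 of 48171 at an unadjusted p under 0.05 against 2409 if uniform. For limma-voom it was 0 genes, with 361 of 18647. Without replicate 4 at 1 mg/kg 1445 genes had an unadjusted p under 0.05, and without replicate 4 at 5 mg/kg 200. The median half-width of the 95% interval of a log2 fold change was 0.53.

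The following values did not pass the test. The smallest unadjusted p (0.000307) belonged to ENSMUSG00000118642, an ID without a symbol or a position in the annotation used here. It lay at 21.6 ± 5.41 CPM at 5 mg/kg and 12.6 ± 1.30 CPM at 1 mg/kg (mean ± SD, n = 6 each), a log2 fold change of 0.77 ± 0.16 (SE). Every library at 5 mg/kg, from 15.5 CPM up, lay above the highest at 1 mg/kg, 14.2 CPM. Such a separation of the groups, in either direction, was found for 8 of 18647 genes, Top1 and Brix1 among them, against 40.4 expected by chance. Pcdh20 (GRCm38 chromosome 14, 88464743 to 88471396, minus strand, protein coding) had a log2 fold change of 0.92 ± 0.25, from 1.20 ± 0.292 to 2.26 ± 0.702 CPM. For Pcsk4, a proprotein convertase, the log2 fold change was 0.97 ± 0.29, and for Rap1gap it was 0.70 ± 0.21. Nr2f6, an orphan nuclear receptor, was at 0.44 ± 0.14, Inafm1 at 0.40 ± 0.12 and Med16, a subunit of the Mediator complex, at 0.32 ± 0.10.

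Agps (GRCm38 chromosome 2, 75832177 to 75931350, plus strand, protein coding) was at 83.0 ± 13.6 CPM at 5 mg/kg and 168 ± 80.8 CPM at 1 mg/kg (n = 6 each). Its log2 fold change was -1.02 ± 0.30 (SE, unadjusted p = 0.00543 by edgeR, adjusted p = 0.943). The 5 mg/kg libraries ran from 62.4 to 102 CPM and the 1 mg/kg libraries from 55.0 to 305 CPM. Hsph1 had a log2 fold change of -0.60 ± 0.19, with 16.3 ± 2.08 CPM at 5 mg/kg against 24.7 ± 7.27 CPM. For Banp, a nuclear matrix-binding protein, it was -0.76 ± 0.27. Smaller values with narrow spreads were found for Togaram1, a cilium protein (-0.31 ± 0.090), Upf2 (-0.29 ± 0.092), Top1 (-0.27 ± 0.085), Brix1, a ribosome assembly factor (-0.26 ± 0.091), and Lin9 (-0.30 ± 0.11). Ints8, a subunit of the Integrator complex, was at -0.38 ± 0.13, Spns2 at -0.37 ± 0.13, Hook1 at -0.34 ± 0.13 and Gpr137c at -0.45 ± 0.17. Rap1gap, Togaram1, Myl3, Krt10, Kng2 and Banp overlap other annotated genes, so part of their counts is uncertain.

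No gene of folate metabolism passed the threshold. The trifunctional enzyme Mthfd1 was at 19.7 ± 3.52 CPM at 5 mg/kg and 18.8 ± 2.46 CPM at 1 mg/kg, a log2 fold change of 0.071 ± 0.14 with a 95% interval from -0.22 to 0.36. Methionine synthase, Mtr, was at -0.13 ± 0.11. The reduced folate carrier Slc19a1 was at 0.27 ± 0.19. The folate receptor Folr1 was scarcely detected, at 0.425 ± 0.225 and 0.507 ± 0.343 CPM. Sardh, the mitochondrial sarcosine dehydrogenase, had the smallest p of the list (0.0406 by edgeR, adjusted p = 0.943), with a log2 fold change of 0.49 ± 0.22. Aldh1l1, which oxidizes formyl-folate, was at 0.57 ± 0.32 and Gnmt, which methylates glycine, at 0.93 ± 0.48, though scarcely detected at 0.448 ± 0.309 and 0.234 ± 0.105 CPM.

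Of the 33 tested genes of 1-carbon and folate metabolism, 21 were higher and 12 lower at 5 mg/kg, with a median of 0.071, and the median difference of log2 CPM turned from 0.087 to -0.074 when libraries were scaled by size alone. By camera with a preset correlation the list ranked above the other genes (adjusted p = 0.0439), but not with an estimated correlation (adjusted p = 0.576). The preset call also ended without replicate 2 or 4 at 5 mg/kg or without replicate 2, 3 or 6 at 1 mg/kg (adjusted p from 0.0501 to 0.0855). The list level was 2.62 ± 0.067 log2 CPM at 5 mg/kg and 2.48 ± 0.12 at 1 mg/kg (n = 6 each), with an exact permutation p of 0.0498 and an adjusted p of 0.683 over 28 lists. Scaling by library size alone moved the median of all tested genes by -0.16, while TMM and the other scalings left it near 0.

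**Figure D1:**
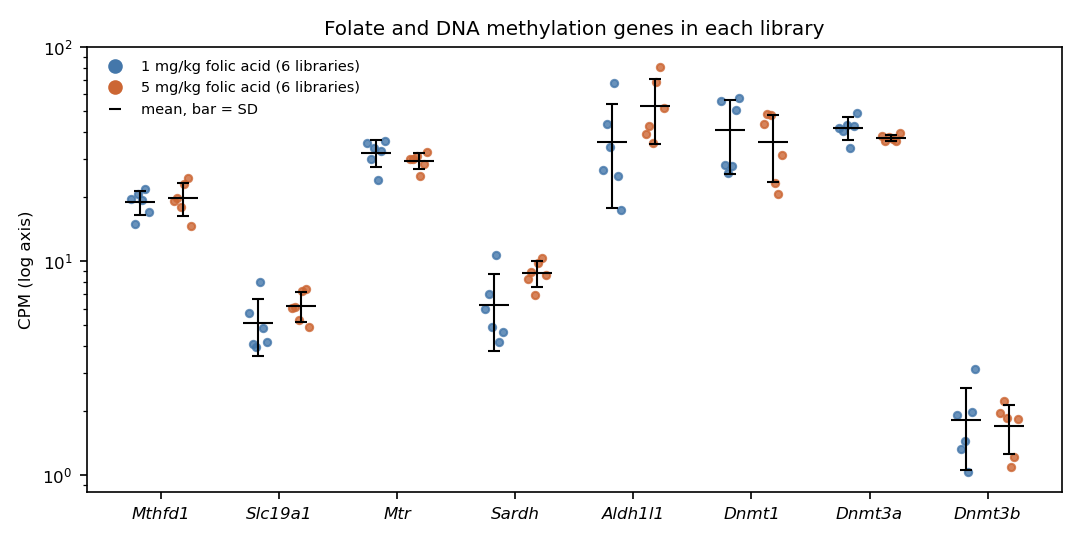
Level of 8 genes of folate metabolism and DNA methylation in CPM on a log axis. Each point is a library (6 per group), the horizontal line is the group mean and the bar the SD. The groups overlap for each gene, and Mthfd1 lies at 19.7 CPM at 5 mg/kg and 18.8 CPM at 1 mg/kg.

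Of the 21 tested genes of DNA methylation and demethylation, 17 were lower at 5 mg/kg, with a median of -0.13. The maintenance methyltransferase Dnmt1 was at -0.20 ± 0.29, the de novo methyltransferases Dnmt3a and Dnmt3b at -0.16 ± 0.093 and -0.094 ± 0.28, the hydroxylase Tet2 at -0.19 ± 0.11 and Uhrf2, which binds hydroxymethylated DNA, at -0.26 ± 0.11 (SE). Camera ranked the list lower with the preset correlation (adjusted p = 0.0173) and not with the estimated one (adjusted p = 0.590). The preset call also ended without replicate 4 or 5 at 5 mg/kg or without replicate 5 or 6 at 1 mg/kg (adjusted p from 0.0504 to 0.0834). Dnmt1 lay at 43.6 CPM or more in the 6 libraries highest in B cell level, which came from both groups. It lay at 31.2 CPM or less in the others. The list level was above 3.41 log2 CPM in those 6 libraries and at 3.41 or less in the others. The list level thus varied with the B cell level within both groups, and whether intake also moved it was not decided. Imprinted genes, whose expression from 1 parental copy depends on methylation, did not pass (23 of 32 higher, median 0.16, camera adjusted p = 0.0507). Among them Gnas was at 0.27 ± 0.21 and Ndn at 0.37 ± 0.23.

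Genes of fat tissue and lipid synthesis were mostly higher at 5 mg/kg. All 22 tested genes of fatty acid and triglyceride synthesis had a positive log2 fold change, with a median of 0.67. Acacb, the acetyl-CoA carboxylase of the mitochondrial surface, was at 0.78 ± 0.35, from 145 ± 62.4 to 250 ± 111 CPM (n = 6 each). The lipogenic transcription factors Srebf1 and Mlxipl were at 0.63 ± 0.28 and 0.69 ± 0.32, and the desaturase Scd1 at 0.40 ± 0.45. Of 20 adipocyte identity genes, 19 were higher, with a median of 0.36, among them the regulator Cebpa (0.58 ± 0.27) and Lipe, the hormone-sensitive lipase (0.53 ± 0.27). Car3, the member with the highest mean CPM, was at -0.055 ± 0.32. Of 23 genes of cholesterol synthesis and uptake, 20 were higher, with a median of 0.29, including Insig1, a regulator of sterol synthesis (0.59 ± 0.39). No member passed, over all genes or adjusted over the list alone.

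Collagens and other matrix genes of fibroblasts were higher in 21 of 22 cases, with a median of 0.44. Col3a1 was at 0.61 ± 0.29, Col6a2 at 0.50 ± 0.22, the crosslinking enzyme Loxl1 at 0.55 ± 0.26 and the protease inhibitor Timp1 at 0.75 ± 0.32 (SE). Replicate 6 at 5 mg/kg held the most Col3a1 and Col6a2 of all libraries, 2237 and 187 CPM. The lowest levels of the matrix list, 5.91 and 5.75 log2 CPM, lay in replicates 5 and 6 at 1 mg/kg. The 14 endothelial genes had 13 higher members and a median of 0.17, with Tie1, a vascular receptor kinase, at 0.27 ± 0.12. Pecam1, the endothelial member with the highest mean CPM, was at -0.072 ± 0.14. All 31 nuclear genes of oxidative phosphorylation were higher, with a median of 0.48, Cox6a1 at 0.75 ± 0.37 and Atp5b at 0.47 ± 0.35. Replicates 4 and 5 at 5 mg/kg had the highest levels of this list (7.21 and 7.45 log2 CPM), of skeletal muscle (9.77 and 10.27) and of brown fat (4.99 and 5.19), and with the muscle level as covariate Atp5b was at -0.091. Camera with the preset correlation ranked these 6 lists of fat, lipid, matrix, vessel and oxidative genes higher. The adjusted p was 2.24e-09 for fatty acid synthesis, 2.52e-08 for adipocyte identity, 2.41e-05 for cholesterol synthesis, 8.17e-11 for matrix, 0.000715 for endothelium and 1.55e-08 for oxidative phosphorylation. With an estimated correlation none of the 28 lists was called, and the adjusted p of these 6 was 0.576, except 0.673 for oxidative phosphorylation. The fry test called none either, with a smallest adjusted p of 0.668, and the levels of these lists did not differ by exact permutation (adjusted p = 0.683 for each). In the same libraries the B cell list level was 2.52 ± 3.30 log2 CPM at 5 mg/kg and 3.28 ± 3.52 at 1 mg/kg, and reads outside genes made up 11.8 ± 5.43% and 15.1 ± 6.61%.

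**Figure D2:**
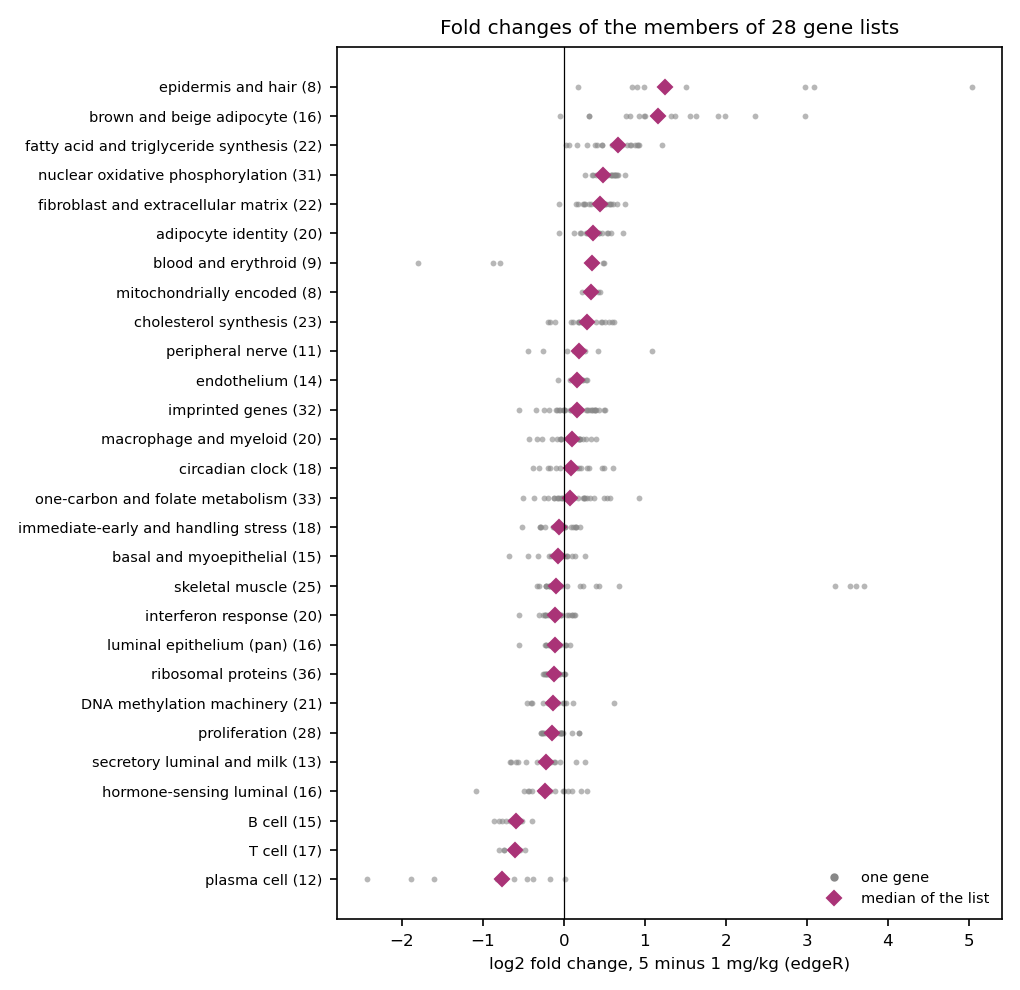
Log2 fold change, 5 minus 1 mg/kg, of each tested member (grey points) of the 28 gene lists, with the list median as a diamond and the number of tested members in parentheses. Fatty acid and triglyceride synthesis has a median of 0.67 and the B cell list one of -0.59, and 4 skeletal muscle genes lie apart at the right of their list.

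Brown fat genes were higher at 5 mg/kg in 15 of 16 cases, with a median of 1.16. The uncoupling protein gene Ucp1, which lets brown fat make heat, was at 415 ± 374 CPM at 5 mg/kg and 111 ± 151 CPM at 1 mg/kg (log2 fold change 1.91 ± 1.15). It ran from 0.902 to 869 CPM within the 5 mg/kg group. Acot11, an acyl-CoA thioesterase of brown fat, was at 2.36 ± 0.87, Kng2 at 2.97 ± 0.96 and the transcription factor Zic1 at 1.64 ± 0.65. Replicates 1, 4 and 5 at 5 mg/kg held 104, 108 and 178 CPM of Acot11, and the rest of that group 2.84 to 20.8 CPM. At 1 mg/kg it ran from 3.88 to 40.4 CPM. Replicates 4 and 5 at 5 mg/kg were also the highest in skeletal muscle. Camera ranked the list higher with the preset correlation (adjusted p = 4.37e-06) and not with the estimated one (adjusted p = 0.576).

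Skeletal muscle transcripts were present in each library, with a list level from 7.14 to 10.27 log2 CPM. Genes of the slow-twitch troponin complex had positive log2 fold changes by edgeR, most of the remaining muscle genes did not, and no member passed, over all genes or adjusted over the list alone (smallest adjusted p = 0.101). Tnnt1 was at 90.9 ± 113 CPM at 5 mg/kg and 8.89 ± 10.2 CPM at 1 mg/kg (log2 fold change 3.35 ± 1.06, edgeR unadjusted p = 0.00770). Replicates 4 and 5 at 5 mg/kg held 139 and 299 CPM of it, while replicate 6, at 4.09 CPM, lay below replicates 2, 4 and 6 at 1 mg/kg (11.5, 9.44 and 27.6 CPM). Tnni1 was at 3.70 ± 1.22, Tnnc1 at 3.61 ± 1.23 and the slow myosin light chain Myl3 at 3.70 ± 1.17. The giant muscle protein gene Ttn was at -0.19 ± 0.43. Of the 25 listed genes 10 were higher and 15 lower by edgeR, with a median of -0.10, whereas on log2 CPM 21 were higher, with a median of 0.12, or 10, with a median of -0.039, with scaling by library size alone. The mean level was higher by 0.71 and camera with the preset correlation ranked the list higher (adjusted p = 0.0109). With an estimated correlation the adjusted p was 0.761. The preset call also ended without replicate 4 or 5 at 5 mg/kg or without replicate 1, 4 or 6 at 1 mg/kg (adjusted p from 0.0952 to 0.470).

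Epidermal genes were higher in all 8 tested cases, with a median of 1.25 (camera adjusted p = 0.00134, and 0.576 with an estimated correlation). Without replicate 4 at 5 mg/kg, Sprr1a and Lgals7 turned to lower, with log2 fold changes of -0.093 and -0.32. Dmkn was at 3.83 ± 7.07 CPM at 5 mg/kg and 0.116 ± 0.0642 CPM at 1 mg/kg, and the differentiation keratin Krt10 ran from 0.546 to 28.3 CPM at 5 mg/kg and was at 0.726 ± 0.229 CPM at 1 mg/kg. Replicates 4 and 2 at 5 mg/kg held these values, with 17.9 and 4.29 CPM of Dmkn, while none of the others exceeded 0.421 CPM. The desmosomal cadherin Dsg1a was at 2.98 ± 1.20. By edgeR, 2 of 539 list entries, Dmkn and Krt10, passed when adjusted over the list alone (smallest adjusted p = 0.0249), and neither passed over all genes. Neither passed without replicate 4 at 5 mg/kg (edgeR adjusted p over the list alone 0.0843 for Dmkn and 0.234 for Krt10), and the log2 fold changes fell to 3.15 and 1.30. Neither passed without replicate 1, 3, 4, 5 or 6 at 1 mg/kg (edgeR adjusted p from 0.0523 to 0.0778 over the 2 genes). There the log2 fold changes stayed at 4.82 to 5.19 for Dmkn and 2.97 to 3.24 for Krt10. Without replicate 2 at 5 mg/kg Krt10 did not pass (edgeR adjusted p = 0.0515). DESeq2 p-values adjusted over the list alone gave 11 such genes, with Dmkn, Krt10 and Dsg1a of the epidermis, Tnnt1, Tnni1 and Tnnc1 of slow muscle, and Kng2, Acot11 and Zic1 of brown fat among them.

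No list of mammary epithelial genes was called. The pan-luminal list had 13 of 16 genes lower, with a median of -0.11, while the median difference of log2 CPM was 0.072 with TMM and -0.086 with scaling by library size alone. Its mean level was higher by 0.036 and the camera direction was higher (adjusted p = 0.985). The hormone-sensing luminal list had 12 of 16 lower (median -0.23, camera adjusted p = 0.513). The estrogen receptor gene Esr1 was at 0.21 ± 0.28 and the progesterone receptor gene Pgr at -0.49 ± 0.45, with 25.2 ± 17.8 CPM at 1 mg/kg. Of the secretory luminal and milk list 11 of 13 were lower (median -0.22, camera adjusted p = 0.264), with casein kappa, Csn3, at -0.66 ± 0.44, the alveolar regulator Elf5 at -0.59 ± 0.46 and the epithelial factor Ehf of the pan-luminal list at -0.55 ± 0.40. Xdh of the secretory list was higher, at 0.26 ± 0.25. The basal and myoepithelial list had a median of -0.074, while the median difference of log2 CPM was 0.073 with TMM and -0.087 with scaling by library size alone. Its mean level was higher by 0.017 (camera adjusted p = 0.828).

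Of the 28 lists, the B cell list had the widest range of levels over the libraries, followed by the T cell list. The B cell list level ran from -1.18 to 6.20 log2 CPM and the T cell level from -1.07 to 5.10. In 6 libraries, replicates 1, 2 and 3 at 5 mg/kg and 1, 5 and 6 at 1 mg/kg, the B cell level was 4.94 or more. Replicate 3 at 1 mg/kg lay at 3.36, and the other 5 were at -0.041 or less. The B cell antigen gene Ms4a1 ran from 0.482 to 104 CPM at 5 mg/kg and from 0.554 to 152 CPM at 1 mg/kg. Glycam1, known from milk and from lymph node vessels, ran from 0.824 to 423 CPM and from 0.806 to 519 CPM. Their log2 fold changes were -0.80 ± 1.45 and -0.66 ± 1.55, and those of the complement receptor Cr2 and the interleukin-7 receptor Il7r were -0.86 ± 1.44 and -0.80 ± 1.18. All 15 B cell and all 17 T cell genes and 11 of 12 plasma cell genes were lower at 5 mg/kg, with medians of -0.59, -0.61 and -0.76, and none of the 3 lists was called (camera adjusted p = 0.106, 0.0640 and 0.0507). Exact permutation of the B cell level gave p = 0.729. Macrophage and myeloid genes had a median of 0.10 (camera adjusted p = 0.108), and the median difference of log2 CPM was 0.14 with TMM and -0.020 with scaling by library size alone.

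**Figure D3:**
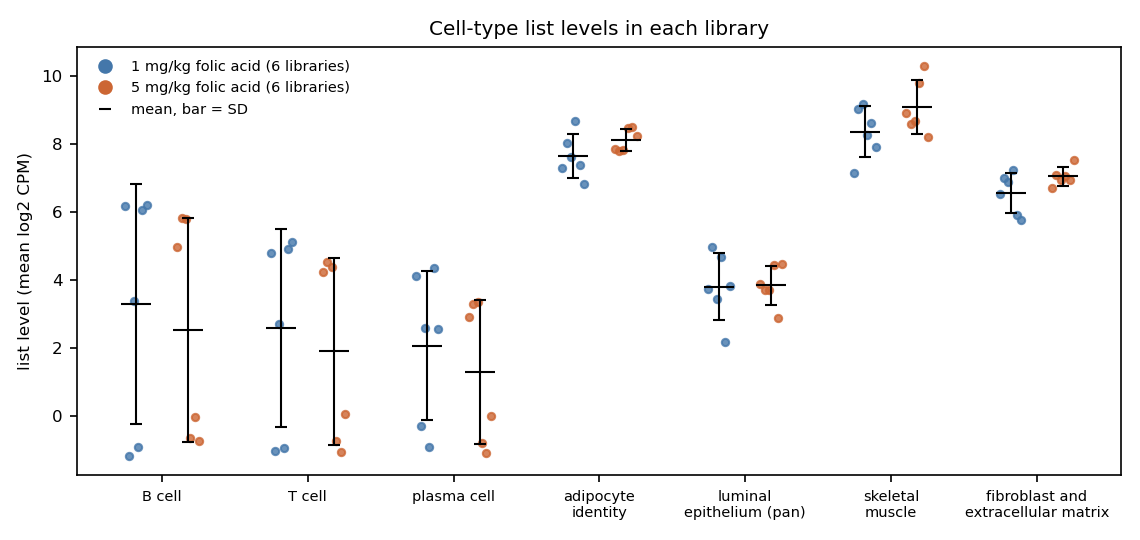
Level of 7 cell-type gene lists, as mean log2 CPM, in each library. Points are libraries (6 per group), horizontal lines are group means and bars the SD. The B cell level runs from -1.18 to 6.20 and both groups hold libraries with high and with low levels.

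No separation of the libraries by folic acid group was detected. The first principal component of the 500 most variable genes held 91.7% of their variance and was led by lymphoid genes such as Glycam1 and Ms4a1. The groups accounted for 3.67% of the sum of squares, and many other splits gave as much (exact permutation p = 0.589 over 462 splits). The highest split reached 81.0%. Libraries lay 0.598 ± 0.0890 log2 units from their group centre at 5 mg/kg and 0.659 ± 0.0978 at 1 mg/kg over all tested genes, and the difference was within chance (exact permutation p = 0.468).

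Among the remaining lists, ribosomal protein genes were lower in 34 of 36 cases, with a median of -0.12 and Rpl22 at -0.16 ± 0.13. Camera with the preset correlation ranked them lower (adjusted p = 0.00341), and with an estimated correlation it did not (adjusted p = 0.761). The preset call also ended without replicate 5 or 6 at 5 mg/kg or without replicate 1 or 5 at 1 mg/kg (adjusted p from 0.0656 to 0.432). The ribosomal list level was 6.599 log2 CPM or more in the 6 libraries highest in B cell level, which came from both groups. It was 6.399 or less in the others. The ribosomal level thus varied with the B cell level within both groups, and whether intake also moved it was not decided. The following lists were not called. Mitochondrially encoded genes had a median of 0.33 (camera adjusted p = 0.0530) and interferon response genes one of -0.10 (adjusted p = 0.113), with Ifi44 at -0.30 ± 0.16. Proliferation genes had a median of -0.14 (adjusted p = 0.320), with Mki67 at -0.28 ± 0.53, and blood and erythroid genes one of 0.34 (adjusted p = 0.341). Circadian clock genes had a median of 0.091 (adjusted p = 0.0994), while the median difference of log2 CPM was 0.14 with TMM and -0.019 with scaling by library size alone, with Dbp at 0.47 ± 0.23 and Cry1 at -0.38 ± 0.20. Peripheral nerve genes had a median of 0.19 (adjusted p = 0.264), while the median difference of log2 CPM was 0.13 with TMM and -0.019 with library size alone, with the Schwann cell and fat gene S100b at 1.09 ± 0.47. Immediate-early and handling stress genes had a median of -0.063, which on log2 CPM was 0.0089 with TMM and -0.15 with library size alone (adjusted p = 0.581), with the cytokine signalling inhibitor Socs3 at -0.52 ± 0.33.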

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

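No tests were added for these values, and which named genes were examined was settled after their values were seen. Of 218 sets of 6 libraries examined (quality measures, list levels and named genes in each group), 8 had a library whose distance to the nearest of the others, as a share of the range, exceeded the 95% critical value of Dixon's test. Chance gives 5% of sets, or 10.9 here, so these values are given without an explanation.

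Replicate 6 at 5 mg/kg had the lowest Ucp1 of its group, at -0.098 log2 CPM against 6.81 in the nearest library. It also had the lowest level of the blood and erythroid list, at -0.13 against 0.90, and the highest Col6a2, at 7.55 against 6.73. Replicate 5 at 5 mg/kg had the lowest level of the secretory luminal and milk list, at 2.43 against 3.62, and the lowest Csn3, at 1.34 against 2.92. It also had the highest level of the peripheral nerve list, at 3.30 against 2.64. Replicate 4 at 1 mg/kg had the highest level of the cholesterol synthesis list, at 3.96 against 3.23, and the highest Tie1, at 4.66 against 4.18.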

How the results depend on the processing

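Fits with the share of reads outside genes, fits within libraries of like B cell level, list tests with the B cell level, counts of list members with 1 library left out and removal of mitochondrial rRNA were chosen after seeing the data. No gene passed under any of 32 alternative fits or at the looser threshold of 0.10, and the smallest adjusted p over these fits was 0.259, in the 6 libraries highest in B cell level. The count at an unadjusted p under 0.05 moved from 359 to 1445 without replicate 4 at 1 mg/kg and to 802 without replicate 6 at 5 mg/kg. It fell to 200 and 211 without replicates 4 and 5 at 5 mg/kg, and to 205 and 206 without replicates 1 and 6 at 1 mg/kg. It was 3066 in the 6 libraries highest in B cell level, against 958 if p-values were uniform, and 252 in the 5 lowest. Other splits of those 6 libraries were not examined. With surrogate variables the count was 1248, and with the B cell level and reads outside genes 1228. It was 870 with quality weights, 863, 825, 616 and 529 with the adipocyte, B cell, muscle and luminal levels, 170 with library size alone, and 1677 against 2410.4 expected without a filter. It was 776 of 48171 genes with DESeq2, against 2408.55 expected, and the remaining fits gave from 278 to 524. No paired analysis was possible because the replicate numbers follow record order only. Depth was not varied. In counts simulated at this depth and number of libraries, 73 of 200 changes of 2-fold and 0 of 200 changes of 1.5-fold were called. Genes were drawn independently there, without the shared structure of the real libraries, so these counts need not carry over.

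The 12 list calls of the preset correlation became 0 with an estimated correlation, 0 with fry, and 0 with an estimated correlation and the B cell level as covariate. Between 10 and 19 lists were called when 1 library was left out, the 19 without replicate 2 at 5 mg/kg, and 23 were called in the 6 libraries highest in B cell level. With an estimated correlation 0 were called in each of these fits, with a smallest adjusted p of 0.364 with 1 library left out and 0.316 in the 6 libraries. The cause was not tested. List members passing when adjusted over the list alone numbered 2 by edgeR and 11 by DESeq2. With 1 library left out they ran from 0 to 21, with 0 without replicate 4 at 5 mg/kg or replicate 1 or 5 at 1 mg/kg, 1 without replicate 2 at 5 mg/kg and 21 without replicate 4 at 1 mg/kg. They were 10 without replicate 6 at 5 mg/kg, 11 without replicate 3 at 1 mg/kg, 4 without replicate 1 at 5 mg/kg and 4 without replicate 6 at 1 mg/kg. The difference in library spread was -0.061 over all genes and 0.016 over the 500 most variable, within chance in both. The 5 libraries lowest in B cell level were replicates 4, 5 and 6 at 5 mg/kg and 2 and 4 at 1 mg/kg. They were picked by that level, which ran only from -1.18 to -0.041 log2 CPM among them. Some lists turned direction with a call there. The camera adjusted p with the preset correlation was 5.41e-10 for pan-luminal, 5.41e-10 for basal, 2.11e-07 for B cell, 0.000139 for T cell, 0.0139 for proliferation and 0.0231 for interferon response. There an estimated correlation called 0 lists (smallest adjusted p = 0.756) and fry 0 (smallest adjusted p = 0.973). Lists not called with all libraries were called in some fits with 1 left out, among them T cell (adjusted p down to 0.000342), B cell (0.000862), plasma cell (0.00179) and imprinted genes (0.00235). With an estimated correlation and with fry 0 lists were called in any of these fits (smallest adjusted p 0.364 and 0.140). In the 6 libraries highest in B cell level fry called 1 list, endothelium (adjusted p = 0.0145), and 6 when tested in either direction. The pan-luminal list had adjusted p from 0.00529, turned to lower without replicate 5 at 1 mg/kg, to 0.992 with 1 library left out. The cause was not tested.

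Of 75 named genes examined, 56 kept their sign in each alternative fit, and of 2390 fitted values 65 had the other sign, none past the threshold. Car3, Pecam1 and Xdh were not among the genes examined. With the adipocyte level as covariate the log2 fold changes with turned sign were 0.029 for Mtr, 0.20 for Dnmt1, 0.37 for Dnmt3b, -0.088 for Esr1, 2.52 for Glycam1, -0.094 for Scd1, 2.36 for Ms4a1, 2.37 for Cr2, 1.67 for Il7r and 0.71 for Mki67. With the muscle level they were -0.052 for Mthfd1, 0.20 for Dnmt1, 0.18 for Dnmt3b, 0.28 for Glycam1, 0.55 for Ms4a1, -0.091 for Atp5b, -0.039 for Gnas, 0.50 for Cr2, 0.20 for Il7r and 0.36 for Mki67. With the B cell level they were 0.031 for Dnmt3b, 0.17 for Glycam1 and 0.089 for Mki67. With surrogate variables they were -0.033 for Mthfd1, 0.079 for Dnmt1, 0.15 for Dnmt3b, 0.050 for Glycam1, 0.025 for Cr2 and 0.28 for Mki67. With quality weights they were 0.083 for Folr1, 0.066 for Dnmt3b, 0.41 for Glycam1, 0.17 for Ms4a1, 0.17 for Cr2 and 0.22 for Il7r. With library size alone it was -0.12 for Mthfd1. With reads outside genes they were -0.050 for Mthfd1, 0.070 for Dnmt1, 0.16 for Dnmt3b, 0.13 for Ms4a1, 0.098 for Cr2 and 0.12 for Mki67, and with the B cell level added -0.045 for Mthfd1, 0.031 for Dnmt1, 0.17 for Dnmt3b and 0.24 for Mki67. In the 6 libraries highest in B cell level they were 0.88 for Folr1, 0.57 for Pgr and 0.21 for Csn3. In the 5 lowest they were 0.063 for Hsph1, 0.10 for Mtr, 0.045 for Dnmt3a, 0.24 for Dnmt3b, 1.67 for Glycam1, 0.61 for Ms4a1, 0.15 for Ttn, 0.68 for Cr2, 0.40 for Il7r and 0.57 for Mki67. With 1 library left out, Folr1 ran from -0.58 to 0.12, Dnmt3b from -0.21 to 0.14, Ttn from -0.35 to 0.097 and Mki67 from -0.48 to 0.024. The cause was not tested.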

Other observations

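Muscle and brown fat gene sets were formed after the values of their members were seen. The slow muscle set (Tnnt1, Tnni1, Tnnc1, Myh7, Myl2 and Myl3) had a level of 4.92 ± 2.39 log2 CPM at 5 mg/kg and 1.27 ± 2.34 at 1 mg/kg (mean ± SD, n = 6 each). The difference was 3.66, with an exact permutation p of 0.0325, but these genes were chosen after their values were seen, so this p tests nothing about intake. In 3 of the 6 libraries at 5 mg/kg the slow level exceeded every library at 1 mg/kg. The fast muscle set of 12 genes, including the myosin Myh4 and the creatine kinase Ckm, was at 10.16 ± 0.54 and 10.06 ± 1.08. The brown fat set of 8 genes was at 3.16 ± 2.27 and 1.84 ± 1.25 (exact permutation p = 0.242).

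The tests of folic acid as a source of the lymphoid spread, of muscle, of brown fat, of the covariates for the fat lists, and of the gene counts over splits were chosen after the result was seen. The test of lymph node genes and that of lists over splits were set down earlier.

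The first pattern is the wide spread of lymphoid genes, for which folic acid intake as the main source is argued against, since 1.46% of the sum of squares of the B cell level lay between the groups and 3 of the 6 highest libraries came from each. Lymph node tissue in some of the pads is a candidate source. The 6 libraries highest in the B cell list were also the 6 highest in a separate set of lymph node stroma and vessel genes, 4 of whose 6 genes were tested (Cxcl13, the most abundant at 29.8 ± 28.9 CPM at 1 mg/kg, Chst4, Fut7 and Madcam1). All 6 were shared, against 3 expected (exact one-sided p = 0.00108), and lymphocytes gathered outside a node together with such stroma stay open.

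The second pattern is the higher slow muscle genes at 5 mg/kg. Whether a larger amount of the same muscle gives it was not decided. The fast muscle level differed by 0.10 ± 0.49 (SE) and the slow level by 3.66 ± 1.36 in the same libraries. The interval of the slow difference ran from 0.62 to 6.70. The slow genes were chosen for their difference, so the gap is given without a p and cannot exclude this source. A piece of slow muscle cut out together with brown fat could give the pattern. The levels of both sets had Spearman's rho of 0.497 (permutation p = 0.103) and Pearson's r of 0.49 (permutation p = 0.104) over 12 libraries. The 2 libraries farthest from the median slow level were replicates 1 and 3 at 1 mg/kg. Without them rho was 0.685 and r 0.727. Within 5 mg/kg r was 0.893 and within 1 mg/kg, the group of both libraries left out, -0.584. With this few libraries this source can be neither shown nor excluded, and folic acid intake stays open, as untested.

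The third pattern is the higher level of fat, lipid and matrix lists at 5 mg/kg. The mean level of 4 lists (adipocyte identity, fatty acid synthesis, cholesterol synthesis and matrix) differed by 0.48 ± 0.26 (SE, exact permutation p = 0.0909). These lists were pooled after their higher levels were seen, so this p tests nothing about intake. Lymphoid content and reads outside genes were weighed as technical sources. With the B cell level in the model the difference was 0.41 ± 0.19 and with the share of reads outside genes 0.31 ± 0.22. The value plus or minus its SE held 0.24, the middle between 0 and the unadjusted value, in both models, so neither can be excluded as a part of it, and intake stays open.

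Over 100 splits of the 12 libraries into groups of 6, the real one included, the count of 0 genes past the threshold cannot be tested, since all 100 give at least 0, and the highest other split gave 0. Chance was not excluded for the other 2 counts. As many genes at an unadjusted p under 0.05 as the real 359 were given by 51 splits, with 4221 in the highest other and a median of 363 in the others. As many lists as the 12 called with the preset correlation were given by 73 splits, with 22 in the highest other and a median of 13. A split with 4221 genes points to a structure of the libraries, and what gives it was not tested.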
